A study of Mus musculus with 7 samples.

How the data were processed

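RNA from liver and spleen of control mice and of mice with Gaucher disease was measured on 7 Affymetrix whole-transcript gene arrays, 1 array per group, with 3 livers and 4 spleens. Gaucher disease is a lysosomal storage disorder caused by loss of glucocerebrosidase, the enzyme encoded by Gba. The groups were taken from the sample titles: control, mild and severe liver, and control, not enlarged, moderate and severe spleen. Stage refers to the enlargement of the organ. For the severe liver the title, the description and the disease status name liver, while its tissue tag names spleen; the array was used as liver. The labels do not say whether a liver and a spleen came from the same animal, or whether an array holds RNA of a single animal or a pool. The design text of the record speaks of 9 samples and of an exon array, while 7 samples are deposited in the table used here and its probe sets matched a gene array annotation; the difference is not explained in the sources used here.

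The deposited values were probe set intensities on a linear scale, from 9.23 to 27614, with no value at or below 0. The submitters' processing notes name Partek and GCRMA without versions or roles. The background correction, the between-array adjustment and the genome build are not given in the sources used here. Array medians of the deposited intensity lay between 62.1 and 73.0, so the arrays were already on close scales, and no further normalization was made in the main setting. Log2 values had been assumed when the comparisons were planned. Since the values were linear, log2 was taken first and the planned tests were kept. GCRMA-type background handling can leave low values compressed or scattered, so differences between values under an array's median are less certain than those above it. A fold given as at least a value sets each intensity under its array's median to that median. Signal over background, in place of a read depth, sets the precision of each value, and the number of arrays limits it further.

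The table held 35399 probe sets. In the platform annotation used here 23410 of them had a gene name, 21789 with 1 symbol and 1621 with several, and 11989 were unnamed. Names were matched through Entrez identifiers to the RefSeq gene table of the assembly GRCm38.p6, which matched 21698 of the single-symbol probe sets and left 91 with their annotation symbol. That table was used for names and for which genes neighbour each other, with no coordinates printed. Each of 19938 genes was represented by its single-symbol probe set with the highest mean over the 7 arrays. Of these genes 999 had several probe sets, and for 0 genes in either tissue did probe sets differ from control, on average over the disease arrays, by at least 1 log2 unit in opposite directions. Gba was not analysed here, because no probe set carried its name. Probe sets with several genes were named for none. There were 23 of these at least 2-fold higher and 0 lower in every disease spleen, and 3 higher and 12 lower in both disease livers.

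A gene counted as expressed in a tissue when it lay above the array's median over all probe sets in at least 1 array of that tissue, which held for 10575 genes in spleen and 11019 in liver. With 1 array per group no single group can be tested against its control, and no test was made within a tissue, where the stages would have to serve as replicates of each other. Genes were counted instead when they differed from the tissue's control array by at least 1 log2 unit, that is 2-fold, in every disease array. The same control array enters each of these differences, so chance counts were simulated 200 times for unchanged genes, with each gene's spread taken from the disease arrays of the tissue. That spread holds real differences between stages and, by the sex-linked genes, between sexes, which can raise the simulated counts. The overlap of independent lists was computed beside them. Genes in strict order of stage in the disease spleens, with at least 1 log2 unit from the first to the last, were counted beside the 5 other orders of the same arrays.

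Disease was compared with control over all 7 arrays in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with tissue as a covariate, over 11524 genes above the median in at least 2 arrays, with Benjamini-Hochberg adjustment at 0.05. Stages and tissues stand in for replicates there, so the spread holds differences of stage and sex too. A disease by tissue interaction was fitted on the same genes. Each tissue has 1 control array, so its 3 residual degrees of freedom come from differences between the disease arrays, and variation between controls is not measured. Gene lists, 39 of them fixed before the data were examined, were tested with camera at its preset correlation of 0.01, and with an estimated correlation and with fry as alternatives, for the 35 lists with at least 5 members in the fit. Camera asks whether a list differs from the other genes, while the p-value of fry asks whether the list's genes shift in 1 direction regardless of the others. Within a tissue a list's median difference was set among 10000 random lists of the same size matched on mean expression, as a description of these arrays. Where fewer than 5 members were expressed, values are given without a percentile. Members not found under their listed symbols were matched through synonyms. This put Olfr48 in the place of C3 in the complement list and Loxl3 in the place of Loxl2 in the extracellular matrix list.

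The named genes followed a rule fixed before the data were examined. It took Gba, the 12 higher and 12 lower genes per tissue with the largest smallest difference over the disease arrays, and the 6 genes at each end of the stage comparison in each tissue. It also took the 10 higher and 10 lower genes with the smallest limma p among those with an absolute log2 fold change of at least 1, and up to 4 members per list with the largest mean difference. Predicted genes, clone names ending in Rik and receptor or immunoglobulin segments were skipped in the rankings and kept in the counts. Names of the form of BC018473 were not skipped.

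Alternatives fixed in advance were fold thresholds of 1.5 and 3, quantile normalization over all arrays or within a tissue, median centring, no filter or a filter at the 75th percentile, the mean over a gene's probe sets, log2 of the value plus 16, each array left out in turn, other variance models and covariates, and a threshold of 0.1. Alternatives chosen after seeing the data were a floor at each array's median, sex of the animal as a covariate, and counts without the pancreas, sex-biased liver and sex chromosome lists. The sex covariate was read from Xist, above or below the array's median, and the Y-linked genes divided the arrays the same way.

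The calculations were tested on simulated data with 200 genes changed by known folds. Without noise the 2-fold count in every disease array recovered 100% of the changed genes in both tissues with 0 false calls. With the spread between stages as noise it recovered 25.4%, 97.0% and 100% of genes changed 2-, 4- and 16-fold in spleen, with 110 false calls among 10575 genes, and 35.8%, 91.0% and 98.5% in liver, with 440 false calls among 11019 genes. For disease against control over both tissues limma recovered 31.3%, 80.6% and 97.0% at the same folds, with 6 false calls among 11524 genes. For the interaction it recovered 0%, 17.9% and 59.1%, with 2 false calls. Camera called the 1 shifted list and 0 others. Correlation between genes of the size estimated in the arrays was not part of that test. For the 10 lists called for disease against control, the estimates ran from 0.25 (circadian) to 0.943 (neutrophil). The simulated result therefore does not show that the list p-values at the preset correlation hold for these arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.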

Results

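Liver and spleen of mice lacking glucocerebrosidase, a lysosomal enzyme that breaks down glucosylceramide, were profiled with gene arrays at successive stages of organ enlargement, beside a control of each tissue. In Gaucher disease the undegraded lipid collects in macrophages of liver, spleen and bone marrow. The purpose stated for the series was to find genes whose expression relates to the disease or to its severity. There were 3 liver arrays (control, mild and severe) and 4 spleen arrays (control, not enlarged, moderate and severe). With 1 array per group there is no replicate error within a group, and each difference below compares 2 arrays, not 2 conditions. Values are deposited intensities or log2 differences from the control array of the same tissue. The array labelled severe liver had a median hepatocyte list intensity of 8142, against 9015 in the control liver and 29.8 in the severe spleen. Gba itself was not analysed here, so its transcript gives no check of the labels. Sex-linked genes differed between the arrays. Xist, which is transcribed from the inactive X chromosome, stood at 2682 in the mild liver and at 2633 to 3180 in the control, not enlarged and moderate spleens. It stood at 21.4 to 25.3 in the control liver, the severe liver and the severe spleen, which held Y-linked Eif2s3y at 723 to 845. By these genes the control liver and the control spleen differed in sex, so they did not come from the same animal. The sex chromosome list, with fewer than 5 members, had medians of -0.01, -0.05 and 3.87 in the not enlarged, moderate and severe spleens and of -3.51 and -0.15 in the mild and severe livers; with values floored at the array's median, those of the severe spleen and mild liver were 2.18 and -2.03.

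In all 3 disease spleens, genes of red cell formation and of cell division were higher than in the control spleen. The erythroid list had a median log2 difference of 1.86 in the not enlarged, 2.36 in the moderate and 2.06 in the severe spleen, and 22 of its 23 expressed members were at least 2-fold higher in every disease spleen. Kel, which carries the Kell blood group antigen, had an intensity of 193 in the control spleen and of 1215, 1613 and 1485 in the not enlarged, moderate and severe spleens. Rhag and Rhd, proteins of the Rh complex, were higher by 2.64 and 2.61 log2 units in the not enlarged spleen, and by 2.88 and 2.86 in the severe spleen. Epb42, a protein of the red cell membrane skeleton, was higher by 2.39, 2.88 and 2.84. The cell cycle list had medians of 1.44, 2.12 and 1.92, and 27 of its 29 members were at least 2-fold higher in every disease spleen. Its examples with the largest differences were Prc1 (1.86, 2.54 and 2.33), Tpx2, Cenpe and Birc5, all of which act in mitosis. The medians of both lists lay at the 100th percentile of random lists in each disease spleen.

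Over all genes, 352 of 10575 expressed genes were at least 2-fold higher and 10 were lower in all 3 disease spleens. The single arrays gave 399 higher and 66 lower genes in the not enlarged spleen, 977 and 449 in the moderate spleen, and 999 and 549 in the severe spleen. Among the 12 higher genes named by rule, Tmod1, Tspo2, Btnl10, Cldn13, Tlcd4 and Tspan8 stood beside the erythroid list members Kel, Rhag, Rhd, Epb42 and Trim10. Cldn13 was higher by 2.63, 3.50 and 3.21 log2 units, and Tspo2 by 2.83, 3.21 and 2.44. BC018473 was at least 15.7-, 21.9- and 43.0-fold higher, taken against that array's median of 72.6, since its control intensity of 26.0 lay under the lower quartile of 33.8. Of the 12 lower genes named by rule 9 passed 2-fold in all 3 spleens, and Ncr1, Sema5a and Fmo2 did not. Gzma, the cytotoxic granule protease granzyme A, differed by -1.64, -1.53 and -2.48, and Ncr1, a receptor of natural killer cells, by -1.31, -0.93 and -1.56. Ifi206, Ifi209 and Ifi205 of the interferon-inducible Ifi200 family were lower as well, Ifi206 by -3.14, -2.19 and -1.31. Fcmr, the Fc receptor for IgM, differed by -1.02, -1.92 and -1.88. Map3k19, Akr1c18, Adamdec1 and Il22ra2 were the others that passed. Unchanged genes set against the same control gave on average 63.7 higher and 64.6 lower genes in simulation, with at most 87 of either. The 352 higher genes exceeded the simulated maximum, while the 10 lower genes were fewer than the simulated mean. The lower genes thus showed no excess over the simulation, whose spread holds differences of stage and sex that can raise its counts. Independent lists of these sizes would share 3.48 higher and 0.145 lower genes. Part of the difference from these values may come from the shared control array. Without the not enlarged spleen the counts were 759 higher and 338 lower.

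Neutrophil, megakaryocyte, B cell and T cell lists separated the not enlarged spleen from the enlarged ones. The neutrophil and granulocyte precursor list had a median of -1.14 in the not enlarged spleen, with 11 of 18 members at least 2-fold lower, and of 2.72 and 2.78 in the moderate and severe spleens, where all 18 were at least 2-fold higher. S100a8, a calcium-binding protein of neutrophils, had an intensity of 1669 in the control and of 506, 6686 and 6219 in the 3 disease spleens. Ctsg, the granule protease cathepsin G, differed by -1.15, 3.20 and 3.38. The megakaryocyte and platelet list showed medians of -1.03, 1.57 and 0.67, with Clec1b at -1.11, 1.95 and 1.99. The B cell list had medians of -0.27, -1.78 and -1.86, and 17 of 17 members were at least 2-fold lower in the severe spleen. Fcer2a, the B cell receptor CD23, differed by -0.28, -2.07 and -1.98, and the complement receptor gene Cr2 by -0.34, -1.96 and -2.14. T cell medians were 0.07, -1.37 and -1.08, and those of the MHC class II list -0.20, -0.99 and -1.05. For natural killer and cytotoxic cells they were -0.16, -0.94 and -0.98 (-0.63 and -0.60 in the moderate and severe spleens with the floor), and for dendritic cells -0.31, -0.76 and -0.48 (-0.25 in the moderate spleen with the floor). The plasma cell list lay at 0.33, 0.09 and 0.04, and the stem and progenitor list at -0.27, 0.05 and -0.57 (-0.18 in the severe spleen over all measured members), with Myb higher by 1.67 and 1.68 in the moderate and severe spleens.

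Lipid-laden macrophage genes were highest in the severe spleen, and resident macrophage genes lowest. The list of lipid-laden and Gaucher-associated macrophages had medians of 0.08, 0.35 and 2.03, and 16 of its 20 expressed members were at least 2-fold higher in the severe spleen. Gpnmb, a glycoprotein of lipid-laden macrophages, had an intensity of 323 in the control and of 477, 617 and 5757 in the disease spleens, and Atp6v0d2, a subunit of the proton pump, was higher by 4.59 log2 units in the severe spleen. The pan-macrophage list had medians of -0.18, 0.22 and 0.70. Resident tissue macrophage genes lay at -0.45, -0.33 and -0.84, and the scavenger receptor gene Cd163 differed by -0.76, 0.58 and -3.71. Lysosomal genes had medians of -0.05, 0.03 and 0.44, with 7 of 43 at least 2-fold higher in the severe spleen, among them Ctsl at 2.63 and Gla at 2.36. Sphingolipid metabolism genes lay at -0.04, 0.06 and 0.40, with Sgms2, a sphingomyelin synthase, at -0.26, 2.46 and 2.54. The severe spleen also differed from the other spleens in markers unrelated to these lists. Its exocrine pancreas genes had a median of 3.29, with 14 of 14 at least 2-fold higher, against -0.02 and 0.02 in the not enlarged and moderate spleens, and of 2.12 with values floored at the array's median. Its Xist was at least 45.8-fold lower than in the control spleen and its Eif2s3y at least 11.6-fold higher.

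**Figure D1:**
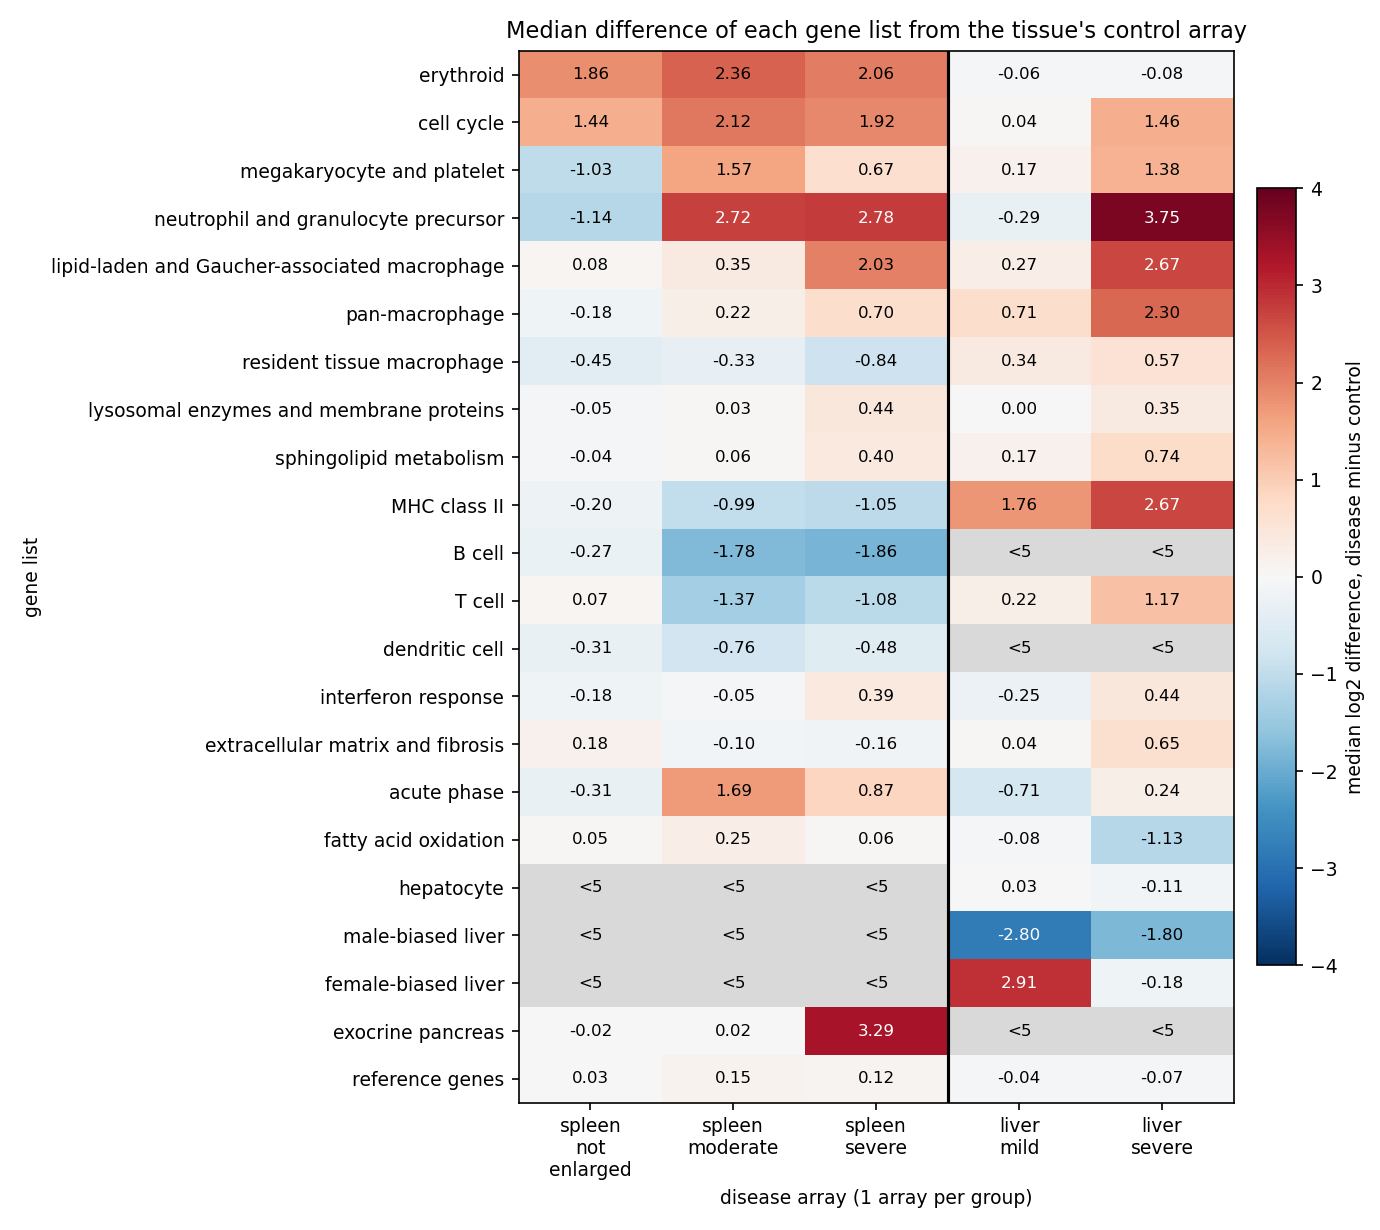
Median log2 difference of 22 gene lists (rows) from the control array of the same tissue in the 3 disease spleens and 2 disease livers (columns, 1 array each); grey cells marked <5 had fewer than 5 expressed members. Erythroid and cell cycle genes were higher in all 3 disease spleens (1.86 and 1.44 in the not enlarged spleen), while neutrophil genes lay at -1.14 in the not enlarged spleen and at 2.72 and 2.78 in the moderate and severe spleens.

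Antigen presentation genes were higher in both disease livers than in the control liver, and most macrophage genes in the severe liver. By Xist and the Y-linked genes the mild liver differed in sex from the control liver, while the severe liver did not. Disease and sex therefore cannot be told apart in the differences of the mild liver. The MHC class II list had a median of 1.76 in the mild and 2.67 in the severe liver (1.20 and 1.98 over all measured members), and 4 of its 6 expressed members were at least 2-fold higher in both. H2-Ab1 had an intensity of 234 in the control, 910 in the mild and 2451 in the severe liver. Cd74, the invariant chain of MHC class II, was higher by 1.98 and 3.48 log2 units. The pan-macrophage list had medians of 0.71 and 2.30, with 4 of 20 members at least 2-fold higher in the mild and 17 of 20 in the severe liver, among them Lyz2 (lysozyme) at 4.47, Clec7a at 4.44 and Cd68 at 4.19. For lipid-laden macrophages the medians were 0.27 and 2.67, with 5 and 15 of 20 members at least 2-fold higher, and 0 and 5 of 13 resident macrophage genes were 2-fold higher. Gpnmb was at least 5.77-fold higher in the mild and 101-fold in the severe liver, taken against the control array's median of 62.1, since its control intensity of 29.0 lay under the lower quartile of 34.8. Mmp12, a macrophage elastase, was higher by 3.35 and 5.97, Lgals3 (galectin 3) by 1.31 and 4.35, and Cxcl9, an interferon-induced chemokine, by 2.21 and 2.84. Serpinb1a, Slc22a26, Nipal1, Socs2 and BC018473 were the other higher genes named by rule. Neutrophil genes lay at -0.29 in the mild liver (0.07 with values floored at the array's median) and at 3.75 in the severe liver. In the severe liver 16 of 18 were at least 2-fold higher and the floored median was 2.90. The hepatocyte list lay at 0.03 and -0.11, with 0 of 25 members 2-fold different in either liver.

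The lower genes of both livers were led by genes known to be higher in male than in female liver. The male-biased list had medians of -2.80 in the mild and -1.80 in the severe liver, with 9 of 13 members at least 2-fold lower in both. Hsd3b5, a steroid dehydrogenase, was at least 11.1- and 10.9-fold lower, Elovl3, a fatty acid elongase, at least 30.2- and 6.55-fold, and the cytochrome P450 gene Cyp4a12a at least 104- and 3.68-fold. The pheromone carrier gene Mup21 differed by -2.80 and -1.80. Female-biased genes had medians of 2.91 in the mild and -0.18 in the severe liver, and Cyp2b9 and Sult3a1 were at least 80.2- and 108-fold higher in the mild liver. By Xist and the Y-linked genes the mild liver differed in sex from the control liver (Xist at least 43.2-fold higher, Eif2s3y at least 12.3-fold lower), while the severe liver did not (Eif2s3y -0.14, and Xist under the median in both arrays). Slc17a8, Obp2a, Selenbp2, Cyp4a12b, Serpina12, Lama3, Csad and Fgf21 were the other lower genes named by rule, and Fgf21, a hormone of the fasting response, differed by -1.66 and -2.91.

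Over all genes, 74 of 11019 expressed genes were at least 2-fold higher and 56 lower in both disease livers. The mild liver alone gave 248 higher and 172 lower genes, and the severe liver 1075 and 213. Simulated unchanged genes gave on average 228 higher and 230 lower, more than were observed. The simulated spread came from the mild and severe livers alone, which differ in stage and, by the sex-linked genes, in sex. These differences can raise the simulated counts, so the comparison does not show that the observed counts lie below chance. Independent lists of these sizes would share 24.2 higher and 3.32 lower genes. With log2 of the value plus 16 the higher count was 47. Without the sex-biased liver and sex chromosome lists the lower count was 47, since 9 male-biased list members were removed. Sex-biased genes outside these lists stayed in, among them Cyp4a12b, so this is not a count adjusted for sex. Between the tissues, 3 genes were at least 2-fold higher in every disease array (1.59 expected for independent lists among 9455 genes expressed in both): BC018473, the carbonic anhydrase gene Car2 and Ect2, which acts in cytokinesis. These 3 were named after their values were seen. In the severe arrays, 290 genes were higher in both tissues, where independent lists would share 81.6, and 9 were lower in both (3.07 expected). In opposite directions, 51 were lower in the severe spleen and higher in the severe liver (38.3 expected) and 9 the other way (6.55 expected).

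**Figure D2:**
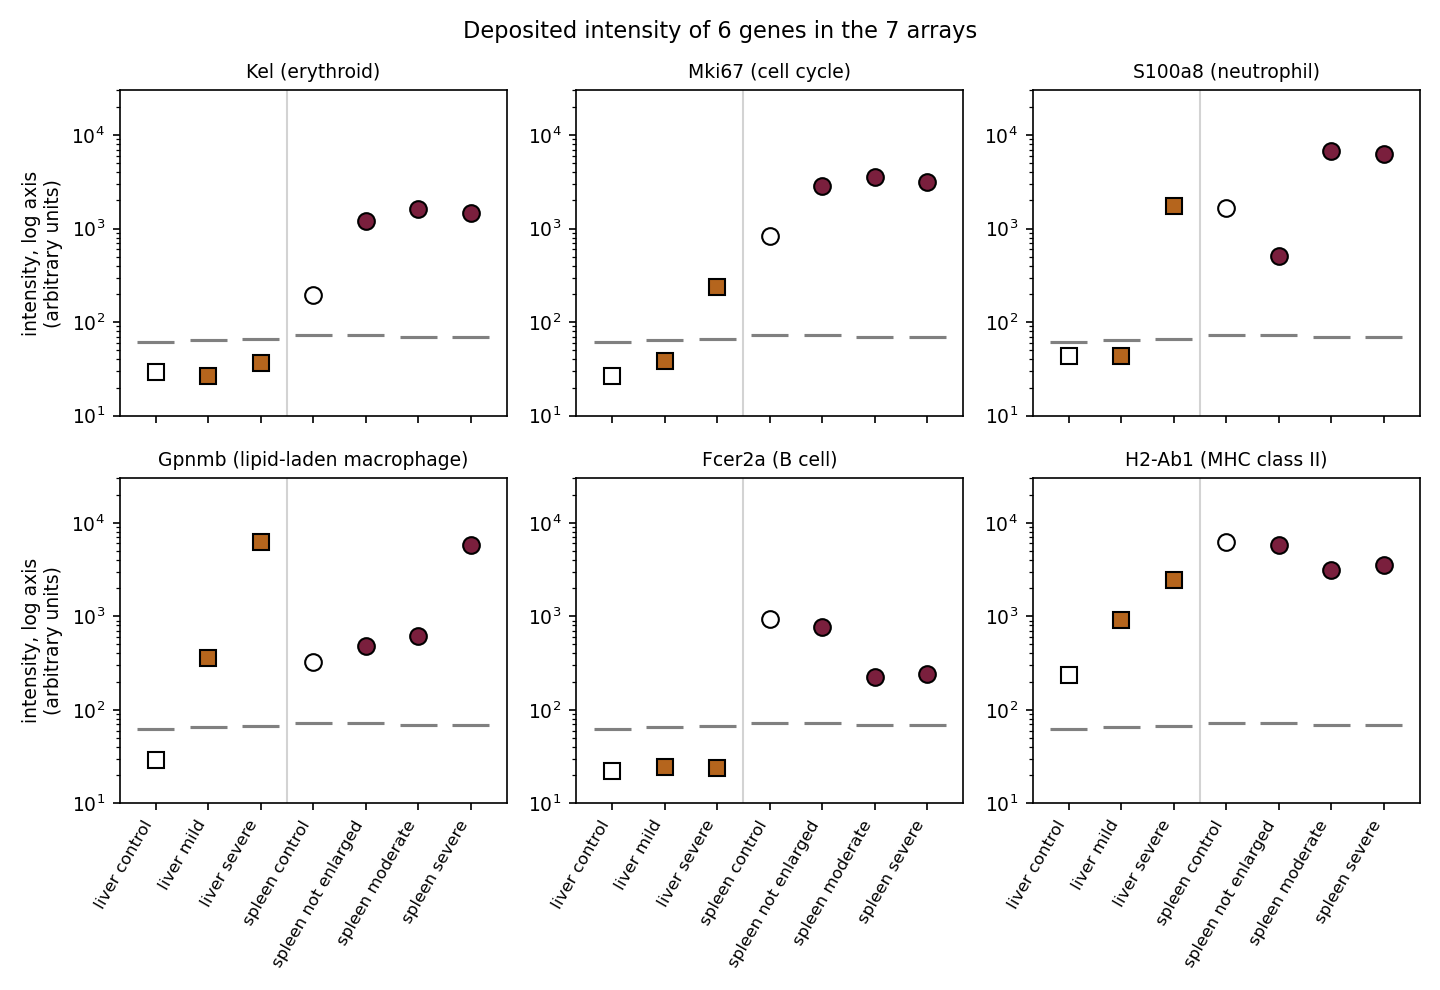
Deposited intensity (log axis, arbitrary units) of 6 genes in each of the 7 arrays; squares are livers, circles spleens, open symbols the controls, and grey bars each array's median over all probe sets. Kel stood at 193 in the control spleen and at 1215 to 1613 in the disease spleens, and Gpnmb at 5757 in the severe spleen and 6282 in the severe liver.

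The series also asked which genes follow severity. In the disease spleens, 377 genes stood in the order not enlarged, moderate, severe with at least 2-fold between the ends, and 283 in the reverse order. The other orders of the same arrays gave 197, 91, 155 and 32 genes, so the not enlarged spleen stood at one end in most of the ordered genes. The ascending genes named by rule were the granulocyte genes Ms4a3, Ctsg and Ly6g, with Ly6a2 and the pancreatic genes Cpa1 and Cpb1. From the not enlarged to the severe spleen Ms4a3 differed by 5.28 log2 units and Ly6g, the neutrophil marker, by 4.43. Cpb1 differed by 5.44, and its values in the not enlarged and moderate spleens lay within 0.10 of the control. Ms4a3, Ly6g, Cpa1 and Cpb1 lay under the array's median in the not enlarged spleen, so the size of their differences is uncertain. The descending genes were Xist, Apol7c, Rgs13, Ctla4, Pdk4 and Fcrl5. By Xist and the Y-linked genes the severe spleen differed in sex from the not enlarged and moderate spleens. Severity and sex therefore cannot be told apart in genes that set the severe spleen apart. The exocrine pancreas list was also higher in that array alone, with a median of 3.29 against 0.02 in the moderate spleen. The ordered counts hold such genes, among them Cpa1 and Cpb1, and were not repeated without them. Ctla4, a T cell checkpoint receptor, differed by -2.45, and Rgs13, a signalling regulator of germinal centre B cells, by -2.47. With a filter at the 75th percentile 170 genes were in descending order.

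Between the severe and the mild liver, 1036 genes were at least 2-fold higher and 326 lower in the severe liver. Neutrophil genes led the higher genes. Ngp, a neutrophil granule protein, was higher by 7.22 log2 units, S100a9 by 6.00, Ltf (lactoferrin) by 5.82 and S100a8 by 5.33, and male-biased Cyp4a12a and Cyp4a12b were higher by 6.17 and 5.65. These 6 genes lay under the array's median in the mild liver, so the size of their differences is uncertain. The lower genes named by rule were Xist and 5 enzymes of steroid and drug metabolism that are female-biased or close relatives of such genes: Sult3a1, with an intensity of 6693 in the mild and 29.8 in the severe liver, Cyp3a16, with 3274 and 32.5, Sult3a2, Cyp2b13 and Cyp2b9. These 2 arrays differ in sex by the same markers. In the severe liver the cell cycle list lay 1.46 above control, with Mki67, a marker of dividing cells, at least 3.87-fold higher, against a list median of 0.04 in the mild liver. With values under the array's median set to that median, the cell cycle median of the severe liver was 0.79. Extracellular matrix genes lay at 0.04 and 0.65, with the collagen genes Col1a1 and Col1a2 at 2.16 and 2.12 in the severe liver. The lysosomal list had medians of 0.00 and 0.35, with the protease gene Ctss at 0.97 and 3.50, and the sphingolipid list of 0.17 and 0.74, with Ugcg, the synthase of glucosylceramide, at 1.27 and 1.14. Fatty acid oxidation genes lay at -0.08 and -1.13, with 9 of 16 at least 2-fold lower in the severe liver, among them Cyp4a14 at -5.79 and Acot1 at -2.92. T cell genes lay at 0.22 and 1.17, and at 0.20 in the severe liver over all measured members. With fewer than 5 members expressed, the B cell list had medians of 0.35 and 1.63 and the natural killer list of 0.47 and 2.47, and over all measured members those of the severe liver were 0.22 and 0.09. The erythroid list lay at -0.06 and -0.08 (0.22 in the severe liver over all measured members). That of megakaryocytes lay at 0.17 and 1.38, the latter 0.52 over all measured members.

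**Figure D3:**
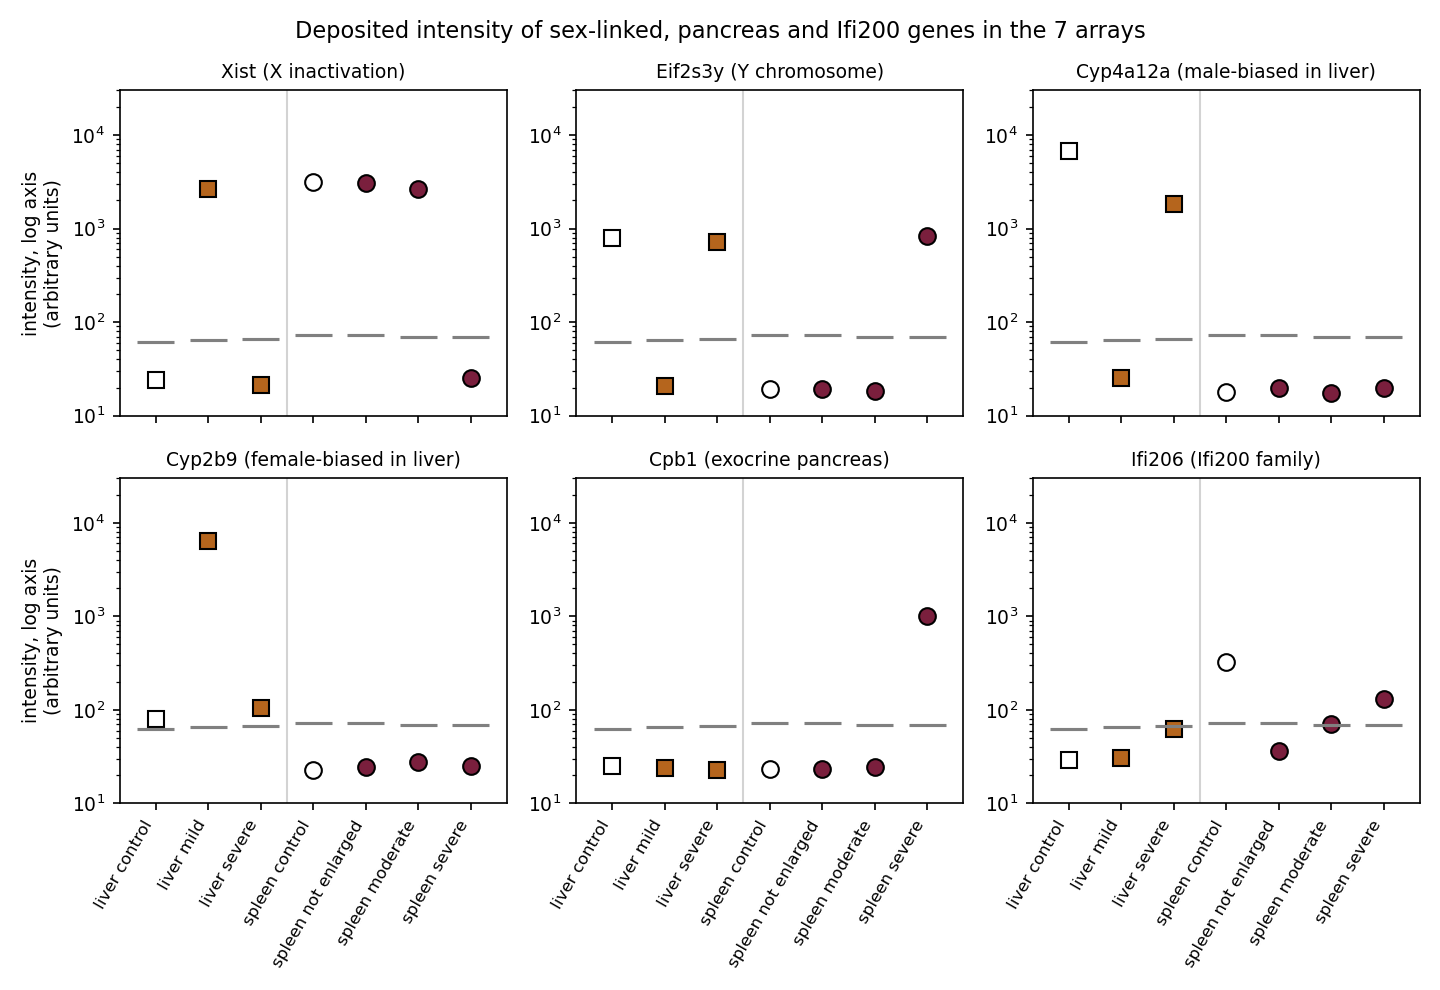
Deposited intensity (log axis, arbitrary units) of Xist, Eif2s3y, Cyp4a12a, Cyp2b9, Cpb1 and Ifi206 in each of the 7 arrays; squares are livers, circles spleens, open symbols the controls, and grey bars each array's median over all probe sets. Xist stood at 21.4 to 25.3 in the control liver, severe liver and severe spleen, and Cpb1 at 1019 in the severe spleen.

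Disease was also compared with control over all 7 arrays, with 5 disease and 2 control arrays. Among the 10 higher genes with the smallest limma p, Car2 and Car1 are members of the erythroid list. Car2 was higher by 1.72 log2 units (SE 0.223), Car1 by 1.33 (SE 0.269), the red cell glycoprotein gene Gypc by 1.21 (SE 0.207), Ect2 by 1.78 (SE 0.268) and thymidine kinase Tk1 by 1.35 (SE 0.248). BC018473, Gch1, H2bc14, Sass6 and Slc16a10 were the others. All 10 were higher in 5 of 5 disease arrays, and each had a limma adjusted p of 0.850. Most of the lower genes named by the same rule differed mainly in the livers: Csad, an enzyme of taurine synthesis, by -1.19 (SE 0.319) and Mup21 by -1.20 over all arrays. Ly6d, at -1.05, was also lower in the 3 disease spleens. The others were Fam47e, Fgf21, Cyp2u1, Asic5, Serpina12, Elovl3 and Adh6-ps1. Limma called 0 of 11524 genes after adjustment, and 590 had an unadjusted p under 0.05 (470 higher and 120 lower), where 576 are expected by chance. With quantile normalization 0 genes were called and the unadjusted split was 371 higher and 190 lower. The unadjusted count was not stable. With 1 disease array left out it ranged from 296 (without the severe spleen) to 861 (without the mild liver), and with stage as a number it was 1956.

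By camera with its preset correlation, 10 of 35 gene lists differed between disease and control, 5 up and 5 down, and 0 did with an estimated correlation (adjusted p = 0.859 for each of the 10) or with fry. Cell cycle genes rose, with a median of 1.27 over 29 genes and 29 of 29 positive (camera adjusted p = 1.26e-19), and so did erythroid genes, with a median of 1.25 and 22 of 23 positive (adjusted p = 3.68e-13), both at adjusted p = 0.859 with an estimated correlation. Lipid-laden macrophage genes (median 1.01, adjusted p = 0.000934), pan-macrophage genes (0.74, adjusted p = 0.00208) and neutrophil genes (1.70, adjusted p = 0.0110) rose as well, again at adjusted p = 0.859 with an estimated correlation. B cell genes fell, with a median of -0.55 (adjusted p = 7.09e-05), as did male-biased liver genes (-1.05, adjusted p = 2.75e-05), fatty acid oxidation genes (-0.34, adjusted p = 0.00212), circadian clock genes (-0.19, adjusted p = 0.00729) and T cell genes (-0.28, adjusted p = 0.0134), each at adjusted p = 0.859 with an estimated correlation. The fit pools both tissues, and several called lists did not move alike in both. In the mild and severe livers the medians were -0.06 and -0.08 for erythroid, 0.22 and 1.17 for T cell and 0.24 and -0.07 for circadian genes. Fatty acid oxidation genes lay at 0.05, 0.25 and 0.06 in the not enlarged, moderate and severe spleens. Cell cycle and lipid-laden macrophage medians were positive in every disease array. Adjusted over the list alone, 23 of 29 cell cycle genes and 2 of 23 erythroid genes passed limma's threshold, against 0 over all genes tested, and 0 of the 546 listed genes passed when adjusted over all lists together. Lysosomal (adjusted p = 0.244), sphingolipid (adjusted p = 0.114) and dendritic cell (adjusted p = 0.0833) genes did not pass with tissue as the covariate, and passed at the preset correlation when sex was added (adjusted p = 0.0441, 0.0468 and 0.0425). With an estimated correlation and tissue as the covariate each had an adjusted p = 0.859. With 1 array left out there were 20 further passes by lists not called on all arrays, from MHC class II without the control spleen (adjusted p = 2.86e-05) to complement without the moderate spleen (adjusted p = 0.0481), and megakaryocyte, resident macrophage, dendritic cell, lysosomal and sphingolipid genes were among these lists. Without the control spleen the erythroid (adjusted p = 0.801) and neutrophil (adjusted p = 0.107) calls ended and the B cell, T cell and circadian lists turned in direction. Without the control liver the calls of both macrophage lists, neutrophil, fatty acid oxidation and male-biased genes ended. Without the severe liver the pan-macrophage (adjusted p = 0.140), neutrophil (adjusted p = 0.385) and fatty acid oxidation (adjusted p = 0.362) calls ended, and without the severe spleen the neutrophil (adjusted p = 0.0564) and T cell (adjusted p = 0.0639) calls. The T cell call also ended without the mild liver (adjusted p = 0.0621), without the moderate spleen (adjusted p = 0.124) and with quantile normalization (adjusted p = 0.106). Cell cycle was the 1 called list that passed with any 1 array left out, at its weakest without the control spleen (adjusted p = 0.000320).

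Whether the disease effect differed between liver and spleen was tested as an interaction. Limma called 0 of 11524 genes, with 719 at an unadjusted p under 0.05 and a smallest adjusted p of 0.661. Without the severe liver it called 5 genes. By camera with the preset correlation 17 lists passed. Each tissue's control is 1 array, whose variation is not measured, so either control array alone could make a list pass. Of the 23 measured erythroid genes 11 were expressed in liver, so their liver effect rests in part on values under the array's median. The erythroid list was 2.03 log2 units further above control in spleen than in liver (adjusted p = 3.97e-25), and the MHC class II list differed by -2.32, being higher in the disease livers and lower in the enlarged spleens (adjusted p = 2.04e-06). With an estimated correlation 0 lists differed, with adjusted p = 0.609 for the erythroid and 0.640 for the MHC class II list.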

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

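By camera with its preset correlation 17 gene lists passed the interaction test of the disease effect in spleen against liver, and 0 did with an estimated correlation (adjusted p from 0.609 to 0.698). Each tissue has 1 control array, and variation between controls is not measured, so the values below describe these arrays and either control alone can set them. Values are median log2 differences of the effect, spleen minus liver. The effect was further up in spleen for erythroid (2.03), cell cycle (1.27), male-biased liver (1.96), fatty acid oxidation (0.72), cholesterol synthesis (0.50) and neighbours of Gba (0.37) genes. It was further down in spleen for MHC class II (-2.32), B cell (-1.49), pan-macrophage (-1.22), endothelial (-0.75), T cell (-0.86), resident tissue macrophage (-1.03), circadian (-0.74), dendritic cell (-0.89), cytokine and chemokine (-0.58), immediate early (-0.96) and extracellular matrix (-0.66) genes. Adjusted p ranged from 3.97e-25 for erythroid to 0.0485 for the neighbours of Gba. For male-biased liver genes the fit holds 1 control liver of male sex by its markers, a mild liver of female sex and spleens that barely express the list. In liver, 4 of 17 measured B cell, 3 of 12 dendritic cell, 8 of 18 T cell and 11 of 23 erythroid genes were expressed. The liver side of these differences therefore rests in part on values under the array's median. The endothelial list had medians of -0.23, -0.25 and -0.82 in the not enlarged, moderate and severe spleens, and of 0.44 and 0.21 in the mild and severe livers.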

How the results depend on the processing

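The counts within a tissue moved most with the fold threshold and with the arrays that enter them. The floor at the array median, sex as a covariate and the counts without pancreas and sex-related lists were chosen after seeing the data; the other alternatives were fixed before. At 1.5-fold and at 3-fold the spleen counts were 696 and 94 higher and 65 and 1 lower, the liver counts 364 and 21 higher and 183 and 15 lower, the genes ordered by stage in disease spleens 777 and 195 rising and 827 and 54 falling, and the genes different between severe and mild liver 1810 and 488 higher in severe and 1138 and 105 lower in severe; a wider or narrower threshold sets these shifts. At the 75th percentile filter, which tests fewer genes, 5 genes were lower in the disease spleens, 35 lower in the disease livers, 170 ordered by stage as falling and 547 higher in severe than mild liver. With log2 of the value plus 16, which compresses low values, 47 genes were higher in both livers, and with the floor 6 were lower in the spleens. Leaving out 1 disease array moved the spleen counts to between 356 and 759 higher and between 14 and 338 lower, and the liver counts to between 248 and 1075 higher and between 172 and 213 lower. Neither control array can be left out within a tissue. Quantile normalization and median centring kept these counts within 1.5 times. In limma the count stayed at 0 under every alternative run, with smallest adjusted p from 0.0528 (stage as a number) to 0.998 (without the control spleen). The interaction called 5 genes without the severe liver, and between 0 and 5 over the arrays left out; the cause was not tested. The 10 called lists became 0 with an estimated correlation and 0 with fry, and 9 with quantile normalization, where T cell was lost. With sex as a covariate all 10 list calls kept their side of the threshold and the lysosomal, sphingolipid and dendritic cell lists passed it too. That covariate is 1 term shared by liver and spleen. It cannot remove a sex difference present in liver alone, so it does not decide whether sex explains the male-biased liver call. With 1 array left out, 4 called lists turned in direction, none of them past the threshold: pan-macrophage (adjusted p from 3.85e-08 to 0.759, without the control liver), and, without the control spleen, B cell (from 6.28e-08 to 0.732), T cell (from 2.28e-05 to 0.576) and circadian (from 0.000101 to 0.681) genes. No paired analysis was possible because each group holds 1 array and the labels do not tie livers to spleens. Signal over background limits genes under an array's median, whose differences shrank with the floor.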

Other observations

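Iron, stress and acute phase lists were not called by camera for disease against control (adjusted p = 0.389, 0.147 and 0.631), nor was the xenobiotic and bile acid list (adjusted p = 0.423), so their medians describe these arrays. In the iron metabolism list the antimicrobial peptide gene Hamp2 differed by 4.14 log2 units in the mild liver and by -0.03 in the severe liver. By Xist and the Y-linked genes the mild liver differed in sex from the control and severe livers, so sex and stage cannot be told apart there. Steap3, which acts in iron uptake, was higher by 1.61 in the not enlarged spleen. The list's medians were -0.08, 0.34 and 0.54 in the not enlarged, moderate and severe spleens (-0.05 and -0.05 in the moderate and severe spleens over all measured members) and 0.07 and 0.25 in the mild and severe livers. Heat shock and endoplasmic reticulum stress genes lay at 0.35, 0.54 and 0.49 in the spleens and at 0.59 and -0.20 in the livers. Asns, asparagine synthetase, was higher by 1.42, 2.47 and 2.60 in the spleens and differed by -3.41 in the mild liver. Acute phase genes lay at -0.31, 1.69 and 0.87 in the spleens, with Hp (haptoglobin) at 3.06 in the moderate spleen, and at -0.71 and 0.24 in the livers. Over all measured members, most of them not expressed in spleen, the spleen medians were 0.28 and 0.01 in the moderate and severe spleens. Xenobiotic and bile acid genes lay at 0.21 and -0.55 in the livers, with Cyp8b1, a bile acid synthesis enzyme, at -0.74 and -2.86 and Cyp2b10 at 0.24 and -3.31. Cholesterol synthesis genes lay at -0.10, 0.10 and 0.53 in the spleens and at -0.28 and -0.37 in the livers, and fatty acid synthesis genes at -0.08, -0.10 and -0.09, and at 0.42 and 0.28.

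Interferon response genes had medians of -0.18, -0.05 and 0.39 in the 3 spleens, with Rsad2 at 1.98, 1.49 and 2.58, and of -0.25 and 0.44 in the livers. Cytokine and chemokine genes lay at -0.04, -0.34 and 0.23, and at 0.21 and 1.07 (-0.12 in the moderate spleen and 0.65 in the severe liver over all measured members), with Ccl3 at least 5.67-fold higher in the severe liver. Complement genes lay at -0.08, -0.13 and -0.69 in spleen (-0.10 in the severe spleen over all measured members) and at -0.23 and 0.00 in liver, and the complement receptor gene C3ar1 was higher by 3.49 in the severe spleen and 3.89 in the severe liver. The complement list held the olfactory receptor gene Olfr48, matched through a synonym, in the place of C3. Matrix genes of the spleens lay at 0.18, -0.10 and -0.16, with Loxl3 matched in the place of Loxl2 in the same way. Resident macrophage genes of the livers lay at 0.34 and 0.57, and Cd163 differed by -1.11 and -2.62. Plasma cell genes lay at 0.11 and 0.00 in the livers, where Jchain was at least 7.70-fold higher in the severe liver, and stem cell genes at 0.09 and 0.74 (0.20 in the severe liver over all measured members). Circadian clock genes lay at -0.36, -0.73 and -0.62 in spleen and at 0.24 and -0.07 in liver, and immediate early genes at -0.06, -0.22 and -0.06, and at 0.29 and 1.18. Spleen fatty acid oxidation genes lay at 0.05, 0.25 and 0.06 (-0.09 and -0.04 in the not enlarged and moderate spleens over all measured members). Expressed neighbours of Gba lay at -0.02, 0.35 and 0.19 in spleen (-0.05 in the moderate spleen over all measured members), where Pklr, pyruvate kinase of red cells and liver, was higher by 1.91 in the not enlarged spleen, and at 0.00 and -0.22 in liver. The reference gene list had medians between -0.07 and 0.15, with 1 of 11 members at least 2-fold higher in the severe liver. For stem and progenitor, interferon and acute phase genes the median over both tissues was above 0 while camera's direction was down, since camera compares a list with the other genes. Few members of the adipose (4 in liver, 2 in spleen) and skeletal muscle (0 and 1) lists were expressed, and Fabp4 was higher by 2.22 in the severe liver and 1.84 in the severe spleen.

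Of the tests below, the count of neighbouring lower genes was planned before its result was seen, and the others were chosen after. Male-biased liver genes were lower in both disease livers, by medians of -2.80 and -1.80. For the mild liver, a difference in sex is a candidate explanation, since the Y-linked genes had a median difference of -4.18 from the control liver and female-biased genes one of 2.91. For the severe liver the Y-linked genes differed by -0.14 and the hepatocyte list by -0.11, so neither a female source nor a loss of hepatocyte RNA accounts for its -1.80. An effect of disease on the severe liver stays open, since its -1.80 and the spread between male livers cannot be told apart with 1 array each.

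Macrophage and neutrophil genes were higher in the severe liver, where the 47 members at least 2-fold higher had a median of 3.46. Spleen tissue in the sample is one possible explanation, as the tissue tag names spleen. For the median of 36 such genes it would take 41.7% of severe spleen RNA, but 36 erythroid and B cell genes of that spleen gave a median of 0.825% (quartiles -0.114% and 2.08%), and 17 of the 47 were higher in the severe liver than in the severe spleen. The B cell genes Cd72, Cd37 and Cd22 stood apart from that median at 37.7%, 30.9% and 16.3%. The hepatocyte list lay 8.09 log2 units above its level in the severe spleen, which argues against an array that holds spleen. Disease stage stays open as an explanation of the 3.46, and with 1 severe liver it cannot be told apart from differences between samples.

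Genes at least 1.5-fold lower in all 3 disease spleens often lay beside each other. Among 65 such genes there were 19 pairs within 10 neighbouring expressed genes, where 10000 random sets of the same size averaged 3.92, with a 95th percentile of 7 and a maximum of 16. The mice had a mixed background, so a chromosome segment of another strain in the control sample is a candidate explanation. Ifi206, Ifi213, Ifi209, Ifi208, Ifi203 and Ifi205 on chromosome 1 made 15 of the pairs. Of the same family Ifi202b went the other way, by 1.97, 1.52 and 0.08, and Ifi207 was mixed, at -1.71, -0.50 and 0.54. Against the control liver the genes that made these pairs lay between -0.29 and 0.34 in the mild liver. In the severe liver they were higher, by 0.39 to 2.63. Without the family 4 pairs remained, against a 95th percentile of 6. Shared regulation or shared probe sequence of these related genes may therefore explain the excess as well. A general fall of interferon-induced genes is argued against by the interferon list, whose lowest median was -0.18, while the family's medians were -0.96, -1.36 and -1.05; both other explanations stay open, and the 696 higher genes had more pairs than random sets too (541, against a 95th percentile of 487).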
